A study of Caenorhabditis elegans with 43 samples.

How the data were processed

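The data were 43 libraries of total RNA from whole C. elegans of 4 strains. Per the labels, arrested L1 larvae were grown at 25 °C and collected at steps of 2 h. RNA was taken with Tri-Reagent, depleted of ribosomal RNA with Ribo-Zero and made into libraries with ScriptSeq v2. Strain and hour were taken from the labels. The labels do not say whether the libraries of a strain come from separate cultures or from 1 culture sampled repeatedly, so p measures only the spread between these samples.

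The first deposited table holds 1 count per gene and library for 20182 genes, which the authors made from the reads; how reads were mapped and counted, and on which genome build, is not given in the sources used here. 930 genes had a count of 0 in every library. The second deposited table holds log2 values. Checked against the first table, each was the log2 of the count times a common total over the library's own total, plus a pseudocount of 8, so none lies under 3. The common total was 12.02 M in 3 strains and 26.10 M in let-7(n2853). The counts were used for all main values and the log2 values only as an alternative. Gene symbols were taken from the reference table for 18778 IDs, and coordinates from the Ensembl annotation of WBcel235, which held 19513 of the IDs (18772 protein-coding genes, 720 pseudogenes). Mitochondrial and ribosomal RNA genes are not in the table. No pair among 903 pairs of libraries was a duplicate: the smallest chi-square per degree of freedom was 4.36, between the double mutant's 24 and 26 h libraries.

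Libraries held 11.2 to 32.9 M counts. The common dispersion was 0.0178. Genes with a mean CPM of at least 1 over the 40 libraries of 18 to 36 h were tested, 13295 in all. Counts were scaled with TMM and fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test. The model held the hour as a factor with 10 levels and a term per mutant strain and window, early to 26 h and late from 28 h, with 16 columns and 24 residual degrees of freedom. There are no replicate numbers; the hour pairs the libraries of the strains and served as the replicate block, and a fit with no replicate block was an alternative. Adjusted p is by Benjamini and Hochberg over all tested genes, with 0.05 as the threshold. Contrasts were each mutant against N2 in either window and late minus early, let-7(n2853) against the double mutant, and lin-41(xe11) against the double mutant. Standard errors are those of the fitted log2 fold changes. Values per library are CPM, counts over the TMM-scaled library size, and differences per hour used a prior count of 2.

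In N2, the 11 libraries of 18 to 38 h were fitted with a linear trend and a cosine and sine of period 8 h, with 7 residual degrees of freedom. A library's age was the point on the N2 splines with the highest correlation over the oscillating genes. The mean of age minus hour from 20 to 36 h was tested by exact sign flips over 9 hours, adjusted over 3 strains. Lists of genes, 24 in all, were fixed beforehand: heterochronic genes, let-7 targets, LIN-41 targets, L4 and adult cuticle, molting, collagens, vitellogenins, oocyte, germline, sperm, major sperm proteins, vulva, seam cell, epidermis, neuron, muscle, pharynx, intestine, cell cycle, ribosomal proteins, histones, stress and immunity, mitochondrial genes and ribosomal RNA. The last pair had no gene in the table, and 22 lists with at least 3 tested members were tested. Members were counted over all genes and adjusted over the list alone. camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry as a self-contained test. With the preset correlation it called 10, 5, 11 and 6 lists in the 4 late contrasts, and 3, 1, 2 and 1 with the estimated correlation. In the early window it called 8, 5 and 4 in the 3 mutants, and 0, 0 and 0 with the estimated correlation. The heterochronic list had 4 genes rising and 3 falling late in let-7(n2853), 1 rising in lin-41(xe11) and 2 rising in the double mutant. Its shift up in the double mutant (camera, adjusted p = 8.23e-08) was not called with the estimated correlation (0.0749). No molting gene was called late in any mutant.

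Genes were named by a rule. For each late contrast it took lin-41 and all measured members of the LIN-41 target, let-7 target and L4 and adult cuticle lists. It added the 8 largest rises and 8 largest falls among genes past the threshold, with an absolute log2 fold change of at least 1 and the same sign at 5 of 5 late hours, and up to 4 members of each other list with the smallest p. For N2 it took the 5 largest rhythms, rises and falls. Contrasts, tests, lists, rule and most alternatives were chosen before the data were examined. Chosen after seeing the data were ages from all tested genes, the fits without libraries that looked doubtful, without let-7(n2853), with let-7(n2853) thinned to the others' depth or with log2 values rescaled to 1 total, the alternatives for the early effects, and the agreement of late minus early effects. The other genes called in contrasts with 12 or fewer calls were named after their values were seen.

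Alternatives were DESeq2 1.42.0 and its size factors, limma 3.58.1 on the log2 values, other filters on low counts, fits of only the strains compared, another start of the late window, 38 h libraries added, ages in place of hours, and leaving out each hour. Overlaps of calls used Fisher's exact test, and contrasts that share N2 were set beside 20 simulations of noise. For chance, 24 of 126 regroupings of the libraries were refitted, and for the late and early effects all 16 splits, the real one included, that swap the strains within hours.

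The pipeline was tested on simulated data with all 13295 genes. For late effects in let-7(n2853), 73.1%, 89.6% and 100% of genes changed 1.5-, 2- and 4-fold were called, with 19 unchanged genes called, 9.79% of the calls. In lin-41(xe11) it was 68.7%, 85.1% and 100%, with 15 unchanged genes (8.15%), so the share of false calls was above the threshold of 0.05. For late minus early, 46.3%, 74.6% and 92.4% were called in let-7(n2853), with 7 unchanged genes (4.70%). It was 43.3%, 61.2% and 93.9% in lin-41(xe11), with 3 (2.22%). A smaller change between windows was therefore often missed. In N2, 94.5% of simulated rhythms of 4-fold range and 93.5% of trends of 0.2 log2 per 2 h were called, with 6 and 10 unchanged genes. Age shifts of -1, -0.5, 0 and 0.5 h came back as -1.01, -0.51, -0.03 and 0.48 h with ages from all 13295 genes. These libraries were drawn from the same N2 splines that served as the reference. The check therefore does not cover ages from oscillating genes or real spread between libraries.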

Results

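RNA from whole worms, depleted of ribosomal RNA, was sequenced in 43 libraries from 4 strains of Caenorhabditis elegans. They were the wild type N2 (11 libraries), let-7(n2853) (10), lin-41(xe11) (11) and the double mutant lin-41(xe11);let-7(n2853) (11). let-7 is a microRNA that ends larval programmes in the epidermis, and lin-41, one of its best known targets, encodes an RNA-binding protein of the TRIM-NHL family. The n2853 allele is a temperature-sensitive point mutation in let-7, and xe11 alters the let-7 complementary sites in the lin-41 3′ UTR. Each strain was collected at steps of 2 h from 18 to 36 h of growth, and all but let-7(n2853) also at 38 h, with 1 library per strain and hour. In the comparisons, 18 to 26 h made the early window and 28 to 36 h the late window, with n = 5 libraries per strain in each. Changes are log2 fold changes ± standard error, and adjusted p is the Benjamini-Hochberg value of edgeR's quasi-likelihood test over the 13295 genes tested.

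Total counts ran from 11.2 to 32.9 M counts per library. They were 12.6 to 16.12 M in N2, 11.2 to 16.45 M in lin-41(xe11), 12.7 to 25.0 M in the double mutant and 22.9 to 32.9 M in let-7(n2853). The let-7(n2853) libraries were the deepest by median (26.7 M). The double mutant's library of 22 h (25.0 M) was still deeper than that of let-7(n2853) at 18 h (22.9 M). The deposited normalised values of let-7(n2853) had been scaled to 26.10 M counts against 12.02 M in the other strains, a shift of 1.12 log2 units. With those values as they stand the median late change of all genes in let-7(n2853) was 1.11, which turns small falls there into rises, so changes are given relative to the TMM-scaled library. Whether they were prepared or sequenced apart is not given in the sources used here. Any such batch holds 1 strain alone, so it has no within-batch value, and the let-7(n2853) strain and a batch cannot be told apart in comparisons with that strain.

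The first question was when lin-41 RNA (WBGene00003026, on chromosome I from 9334800 to 9342496 in the WBcel235 annotation) falls, and in which strains. In N2 it stood at 225, 198, 187, 173 and 96.8 CPM (counts scaled to library size) from 18 to 26 h. It then stood at 44.3, 38.1, 28.5, 29.6 and 39.2 from 28 to 36 h, and at 81.7 at 38 h. In let-7(n2853) the values were 162, 185, 232, 190 and 148 in the early window and 161, 135, 109, 106 and 108 in the late window. In lin-41(xe11) they were 195, 200, 190, 179 and 124, then 99.1, 102, 68.6, 42.3 and 66.6, and 93.9 at 38 h. In the double mutant they were 173, 194, 231, 184 and 159, then 95.5, 104.2, 69.8, 47.8 and 64.5, and 80.9 at 38 h. Late means of lin-41 were 35.9 ± 6.70 (SD, n = 5) in N2, 124 ± 23.9 in let-7(n2853), 75.8 ± 25.0 in lin-41(xe11) and 76.3 ± 23.2 in the double mutant. Early means of lin-41 lay between 176 ± 48.3 in N2 and 188 ± 27.3 in the double mutant.

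**Figure D1:**
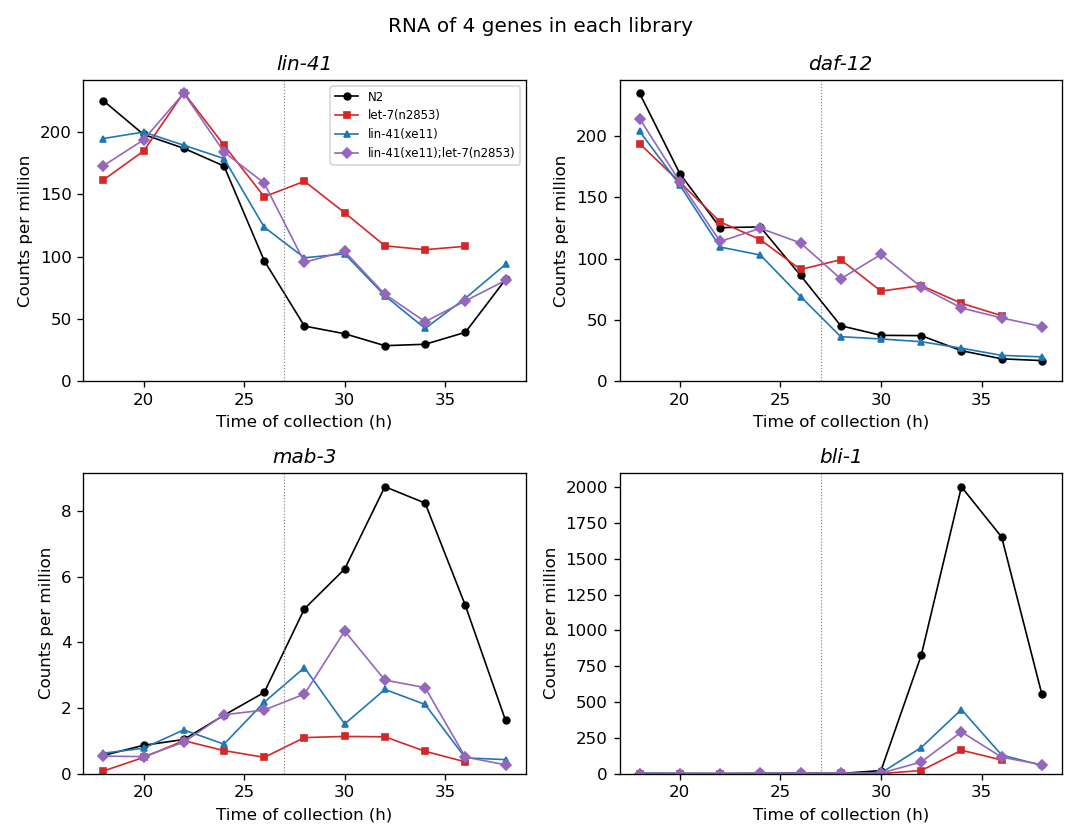
CPM (y axis) against the time of collection in hours (x axis) for lin-41, daf-12, mab-3 and bli-1; each point is 1 library, each colour 1 strain, and the dotted line parts the early from the late window. lin-41 stayed above N2 in all 3 mutants from 28 to 36 h, daf-12 in the 2 strains with the let-7 allele, and mab-3 and bli-1 had lower late means in all 3 mutants.

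The next comparison described how RNA changed along the wild-type time course, from about the third larval stage to young adults. In N2, all 20 germline, all 15 oocyte, all 14 sperm and all 4 major sperm protein genes tested rose. So did all 6 genes of the L4 and adult cuticle list and all 3 tested vitellogenins, the yolk proteins. The vitellogenin vit-2 stood at 0.0616 CPM at 18 h and at 2617.5 at 38 h, and the adult collagen gene col-19 at 0.370 and 1319.95. Genes of larval timing fell: 9 of 10 listed let-7 targets and 16 of 21 heterochronic genes, with 1 heterochronic gene rising. daf-12, which encodes a nuclear hormone receptor, fell by 0.39 ± 0.02 log2 units per 2 h, from 234.9 to 16.8 CPM. hbl-1, a transcription factor gene that delays late larval fates, fell by 0.37 ± 0.03 per 2 h, from 93.9 to 4.05.

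In N2, 17 of 19 neuronal, 10 of 13 seam cell, 8 of 12 pharynx, 8 of 11 epidermal and 15 of 29 molting genes also fell. Of the others in these lists, 1 seam cell and 1 epidermal gene rose. In the cell cycle and replication list 13 of 20 rose and 2 fell, with the mitotic cyclin gene cyb-1 going from 7.64 to 99.3 CPM. The collagen family had 60 of 115 rising and 9 falling. Ribosomal protein genes had 21 of 74 rising and 2 falling, histone genes 9 of 21 rising and 9 falling, and stress and immune genes 6 of 19 each way. Muscle genes had 6 of 15 falling and 1 rising, vulval genes 5 of 19 falling and 2 rising, and intestinal genes 3 of 15 rising and 2 falling. Of the 3 tested genes reported as LIN-41 targets, mab-10 and mab-3 had a rising trend, but mab-10 stood at 8.69 CPM at 18 h and 6.85 at 38 h, and mab-3 at 0.555 and 1.62; the list's median change from 18 to 38 h was -0.33. In total 4390 genes rose and 3628 fell along the N2 time course.

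Among the largest N2 rises were the collagen genes col-122 (0 counts at 18 h, 1134 CPM at 38 h) and col-119 (0.0616 and 881), perm-4 (0 and 105), which belongs to the eggshell, ule-5 (0 and 91.1) and F53H4.2 (0 and 90.4). Among the largest falls were the alpha-tubulin gene tba-8 (108 to 0.295), T19C3.3 (52.8 to 0.810), C05G5.7 (22.8 to 0.295), F17B5.6 (4.07 to 0) and F53F4.7 (3.64 to 0.0737). A rhythm of 8 h on top of the trend, as larval molts give, was called for 416 genes, 267 of them with at least a 2-fold range from peak to trough. It was called for 6 of 29 listed molting genes, such as dpy-10, a cuticle collagen gene (adjusted p = 0.0461). The 5 genes with the largest rhythm, F53H4.2, ttr-14, ZK512.10, Y51H7C.1 and C36E6.8, all started at 0 counts at 18 h and peaked between 34 and 38 h, so for them a late rise and a rhythm cannot be told apart. With periods of 7 and 9 h, 0 and 23 genes were called by the same edgeR test. At a period of 8 h, 3326 genes had an unadjusted p below the threshold.

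The main question was what loss of let-7 does to RNA in the late window. Compared with N2, lin-41 rose by 1.78 ± 0.13 in let-7(n2853) (adjusted p = 1.67e-10) and daf-12 by 1.21 ± 0.09 (5.39e-10), both higher at 5 of 5 late hours. These values rest on n = 5 libraries per strain. Of the 10 listed let-7 targets 4 rose (4 adjusted over the list alone) and none fell. The other 2 were hbl-1 (0.43 ± 0.15, adjusted p = 0.0383, higher at 3 of 5 hours) and nhr-25, a nuclear receptor gene needed for molting (0.63 ± 0.20, 0.0254, 4 of 5 hours). The remaining let-60, die-1, pha-4, lin-14, lin-28 and nhr-23 lay between -0.12 and 0.17 and were not called. hbl-1 was not called when the libraries of 20 h (0.43), 24 h (0.42), 28 h (0.38), 34 h (0.32) or 36 h (0.29) were left out, and nhr-25 not without those of 34 h (0.48) or 36 h (0.41). With an age in place of the hour hbl-1 was not called either (0.24 from all genes, adjusted p = 0.159, and 0.12 from oscillating genes, adjusted p = 0.708). The age from oscillating genes put the let-7(n2853) library of 18 h at 24.8 h and the double mutant's of 22 h at 29.1 h, close to a whole rhythm of 8 h away, while the age from all genes put them at 18 and 21.7 h. A call lost only with the age from oscillating genes therefore says little about timing. Without pairing by hour neither hbl-1 (0.38) nor nhr-25 (0.46) was called. Here and below, that fit counts change between the hours of a window as spread, so a call can be lost with little change in the estimate. The list as a set was shifted up against other genes (camera, adjusted p = 7.16e-06, and adjusted p = 0.0249 with an estimated correlation).

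Genes reported to be repressed by LIN-41 moved the other way in let-7(n2853). mab-3, a DM-domain transcription factor gene of male development, fell by 2.97 ± 0.29 (adjusted p = 4.63e-08) and mab-10, a cofactor of LIN-29 in the switch to adulthood, changed by -1.53 ± 0.26 (9.04e-05), both lower at 5 of 5 hours. lin-29, a transcription factor gene of the same switch, was at -0.26 ± 0.18 (adjusted p = 0.316), and dmd-3 was too low to be tested. Thus 2 of 3 tested members fell, 2 also when adjusted over the list alone. This list is known from work on these strains, so its counts are not independent evidence of its direction. The set was shifted down (camera, adjusted p = 2.04e-04, and adjusted p = 0.0307 with an estimated correlation).

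Cuticle and yolk genes showed the largest falls in let-7(n2853). All 6 tested genes of the L4 and adult cuticle list fell: col-19 (-6.53 ± 0.62, adjusted p = 2.94e-08), col-63 (-4.67 ± 0.54), col-38 (-3.92 ± 0.77), bli-1 (-3.87 ± 0.45), col-49 (-3.63 ± 0.65) and bli-2 (-1.92 ± 0.41). bli-1 and bli-2 encode collagens of the struts of the adult cuticle. The list median was -3.90 (camera, adjusted p = 1.36e-04, but adjusted p = 0.139 with an estimated correlation). Of the collagen family, 48 of 115 fell and none rose (52 fell and 2 rose adjusted over the list alone), among them col-181 (-7.90 ± 0.79), col-175 (-7.65 ± 0.61), col-60 (-6.99 ± 0.85), col-120 (-6.91 ± 1.00) and col-122 (-6.91 ± 0.84). The collagen set test gave adjusted p = 6.59e-06, and adjusted p = 0.219 with an estimated correlation. rol-1, another cuticle collagen gene, fell by 6.14 ± 0.64, and so did col-139 (-5.62 ± 0.78) and col-129 (-5.36 ± 0.80). All 3 tested vitellogenins fell: vit-6 (-9.05 ± 0.82), vit-2 (-6.52 ± 0.50) and vit-1 (-2.07 ± 0.24; camera, adjusted p = 6.59e-06, and adjusted p = 0.0249 with an estimated correlation). Without pairing by hour col-63 (-4.69), bli-1 (-3.98), bli-2 (-2.22) and vit-1 (-2.33) were not called. None of 29 molting genes was called in let-7(n2853) in the late window.

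The oocyte and germline lists had smaller median falls, a difference between lists that was not tested. Of the oocyte list 12 of 15 fell (14 adjusted over the list alone; median -0.58), among them perm-4 (-2.97 ± 0.38), oma-2, which acts in oocyte maturation (-0.93 ± 0.15), and the chitin synthase gene chs-1 (-0.73 ± 0.12). The set test gave adjusted p = 6.37e-08, and adjusted p = 0.139 with an estimated correlation. Of the germline list 10 of 20 fell (13 adjusted over the list alone; median -0.19), such as gld-1 (-0.44 ± 0.11) and cgh-1 (-0.43 ± 0.08), with adjusted p = 4.92e-04 and adjusted p = 0.219 with an estimated correlation. Of the sperm list 1 of 14 fell, nspd-2 (-0.80 ± 0.14), and of the major sperm proteins 2 of 4, msp-64 (-1.26 ± 0.24) and msp-49 (-0.97 ± 0.27), with adjusted p = 0.0121 for the latter set and adjusted p = 0.139 with an estimated correlation. With an age from all genes, gld-1 (-0.21), nspd-2 (-0.23), msp-49 (-0.31) and, of the cell cycle genes below, cyb-1 (-0.15) were not called, and with the age from oscillating genes chs-1 (-0.38) was not either. Without pairing by hour no gene named in this paragraph was called except apx-1 (-1.29). The call of msp-49 was lost without the libraries of 32 h (-0.87), 34 h (-0.86) or 36 h (-1.13). The vulval list had 3 of 19 falling, the Notch ligand gene apx-1 (-1.21 ± 0.18), cog-1 (-0.48 ± 0.13) and ajm-1 (-0.31 ± 0.07), and 1 rising, lin-12 (0.38 ± 0.09). In the cell cycle list 5 of 20 fell, such as cyb-3 (-0.41 ± 0.09) and cyb-1 (-0.37 ± 0.08), and 2 rose, such as rnr-2 (0.38 ± 0.10).

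Of all tested genes 23.05% were called late and 18.5% early in let-7(n2853), which is the share that calls in lists of other tissues stand beside. Ribosomal protein genes had 35 of 74 falling and 3 rising late, and 32 falling and 3 rising early, with rps-29 at -0.82 ± 0.07 late and -1.08 early, and rps-21 at -1.03 ± 0.11 and -0.94. The late set test gave adjusted p = 9.79e-11, and adjusted p = 0.269 with an estimated correlation. Of 15 intestinal genes 7 fell late and 6 early, such as the metallothionein gene mtl-2 (-0.70 ± 0.09 and -0.62) and the brush-border actin gene act-5 (-0.57 ± 0.08 and -0.60). The late intestinal set test gave adjusted p = 3.04e-04, and adjusted p = 0.0902 with an estimated correlation. Muscle genes had 3 of 15 falling and 1 rising late, and 3 falling early, with mlc-3 at -0.46 ± 0.06 and -0.57 early. Stress and immune genes had 6 of 19 rising and 4 falling late, and 6 rising and 1 falling early, with gpdh-1, which makes glycerol under osmotic stress, at 1.34 ± 0.30 and 1.30 early. Late, neuronal genes had 4 of 19 falling and 2 rising, pharynx genes 3 of 12 falling, epidermal genes 2 of 11 falling and 1 rising, histone genes 2 of 21 each way, and 1 of 13 seam cell genes rose (ceh-20, 0.24 ± 0.06). Early, 2 neuronal genes fell and 4 rose, 3 pharynx and 2 histone genes fell, and no epidermal or seam cell gene was called by edgeR. The largest late rises were parg-2 (2.73 ± 0.71), C49G7.12 (2.39 ± 0.50), the P-glycoprotein genes pgp-5 (2.36 ± 0.43) and pgp-6 (1.83 ± 0.39), oac-29 (2.26 ± 0.63), T22B7.7 (2.24 ± 0.33), clec-47 (1.90 ± 0.35) and argk-1 (1.78 ± 0.39). Early, parg-2, C49G7.12 and pgp-5 stood at 3.16, 2.30 and 2.19. parg-2 was not called without the libraries of 30 h (1.97), nor oac-29 without those of 34 h (1.80) or 36 h (1.56). Without pairing by hour oac-29 (1.89), T22B7.7 (2.47), argk-1 (1.63), gpdh-1 (1.42) and ceh-20 (0.21) were not called.

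In all, 3064 of 13295 genes were called between let-7(n2853) and N2 in the late window, 1389 higher and 1675 lower, of which 56 and 198 changed at least 2-fold. Of the calls 45.3% were higher, against 69.2% with limma on the normalised values rescaled to 1 common total, so the balance between rises and falls is not fixed by these data. The count was 566 with no replicate block, that is without pairing libraries by hour, and 1967 without the libraries of 36 h.

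The comparison of lin-41(xe11) with N2 asked what follows when let-7 control is taken away from lin-41 alone. lin-41 rose by 1.03 ± 0.13 in the late window (adjusted p = 4.64e-05, 5 of 5 hours), and daf-12 was at -0.08 ± 0.09 (0.845). mab-3 fell by 1.83 ± 0.29 (adjusted p = 0.00146) and mab-10 stood at -0.94 ± 0.26 (0.113), both lower at 5 of 5 hours. mab-3 was not called with the age from oscillating genes (-1.55, adjusted p = 0.0708) or without pairing by hour (-1.75, adjusted p = 0.792). Again n = 5 libraries per strain. Of the 3 tested LIN-41 targets 1 fell (2 adjusted over the list alone, not independent evidence), and the set was shifted down (camera, adjusted p = 3.43e-05, and adjusted p = 0.0274 with an estimated correlation). Of the 10 let-7 targets only lin-41 itself was called, also adjusted over the list alone; the set test gave adjusted p = 0.00336, and adjusted p = 0.164 with an estimated correlation.

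Cuticle genes fell in lin-41(xe11) as well. Of the L4 and adult cuticle list 2 of 6 fell (6 adjusted over the list alone; median -1.92): col-19 (-2.68 ± 0.47, adjusted p = 0.00408) and bli-1 (-2.38 ± 0.42, adjusted p = 0.00423). The set test gave adjusted p = 5.36e-05, and adjusted p = 0.164 with an estimated correlation. Of the collagen family 11 of 115 fell (23 fell and 1 rose adjusted over the list alone), among them col-181 (-4.86 ± 0.65), col-178 (-3.19 ± 0.49) and col-184 (-3.05 ± 0.64). dao-4 (-2.53 ± 0.48), F58E6.13 (-2.34 ± 0.47), mltn-12 (-1.82 ± 0.37), vrp-1 (-1.06 ± 0.20) and Y39G8B.7 (-1.02 ± 0.20) fell too. The lysozyme gene lys-7 was the only member of the stress and immune list called (-0.74 ± 0.16, adjusted p = 0.0299). bath-13 rose by 1.25 ± 0.16 (1.14e-04), and by 1.49 in the early window. No gene of the vitellogenin, oocyte, germline, sperm, muscle, intestinal or ribosomal protein lists was called by edgeR in this comparison. vit-2 stood at -0.75 ± 0.34 (adjusted p = 0.438), and was called with an age in place of the hour (-1.32 from oscillating genes, -1.13 from all genes). DESeq2 did not call col-19 (-2.40, adjusted p = 0.374), col-178 (-2.65) or dao-4 (-2.31), and limma on rescaled values did not call col-19 (-1.29, adjusted p = 0.434), bli-1 (-2.15, adjusted p = 0.0541), col-181 (-2.22), col-178 (-1.38), col-184 (-1.91), dao-4 (-1.68) or F58E6.13 (-1.81). The calls of most of these falls, though not their direction, rest on the libraries of 34 and 36 h. Leaving out 34 h took away the calls of col-19 (-1.77), bli-1 (-2.45), col-181 (-3.94), col-178 (-2.46), col-184 (-2.44), dao-4 (-2.19), F58E6.13 (-2.10), mltn-12 (-1.87), vrp-1 (-0.95), Y39G8B.7 (-0.96) and lys-7 (-0.54). Leaving out 36 h took away those of col-19 (-3.55), bli-1 (-2.01), col-181 (-4.65), col-178 (-3.83), col-184 (-2.20), dao-4 (-2.17), F58E6.13 (-1.89), mltn-12 (-1.59), Y39G8B.7 (-1.02) and lys-7 (-0.65). Leaving out 32 h took away those of F58E6.13 (-2.38), mltn-12 (-1.69), vrp-1 (-0.98), Y39G8B.7 (-0.95) and lys-7 (-0.79). Y39G8B.7 also depended on 30 h (-0.94), and lys-7 on 18 and 22 h (-0.74 without either). By camera the ribosomal protein set was shifted up (adjusted p = 2.04e-06, but adjusted p = 0.643 with an estimated correlation) and the neuronal set down (0.00645, but adjusted p = 0.213 with an estimated correlation).

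In all, 48 genes were called between lin-41(xe11) and N2 in the late window, 14 higher and 34 lower, of which 3 and 19 changed at least 2-fold. Before adjustment 1341 genes lay below the threshold. The count was 1 with no replicate block, with none of the genes named here called, 7 without the libraries of 34 h and 16 without those of 36 h. The lin-41 call was lost without the pairing of libraries by hour (1.08) and when the hour was replaced by an age estimated from oscillating genes (0.60).

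The double mutant was compared with N2 in the late window in the same way. daf-12 rose by 1.23 ± 0.09 (adjusted p = 1.30e-09) and lin-41 by 1.05 ± 0.13 (1.60e-05), both at 5 of 5 hours. As before, n = 5 libraries per strain. daf-9, a cytochrome P450 gene that makes the ligand of DAF-12, rose by 1.04 ± 0.22 (0.0139), the glutathione transferase gene gst-12 by 1.07 ± 0.23 and Y48E1B.8 by 1.15 ± 0.22. Of the 10 let-7 targets 2 rose (3 adjusted over the list alone), with hbl-1 at 0.57 ± 0.15 (adjusted p = 0.0698), and the set was shifted up (camera, adjusted p = 3.76e-15, and adjusted p = 1.02e-04 with an estimated correlation). mab-3 fell by 1.47 ± 0.28 (0.00426) and mab-10 stood at -0.80 ± 0.25 (0.155). Of the 3 LIN-41 targets 1 fell (2 adjusted over the list alone, not independent evidence; camera, adjusted p = 0.00162, but adjusted p = 0.0749 with an estimated correlation). Without the libraries of 34 h, mab-3 (-1.41), daf-9 (0.88), gst-12 (0.84) and Y48E1B.8 (0.97) were not called, nor without those of 32 h daf-9 (1.09) and gst-12 (1.04). With the age from oscillating genes mab-3 (-1.15), daf-9 (0.84) and gst-12 (0.84) were not called, and without pairing by hour no gene named here was, mab-3 (-1.38), daf-12 (1.20) and lin-41 (1.09) included.

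Of the L4 and adult cuticle list 4 of 6 fell in the double mutant (6 adjusted over the list alone; median -2.45): col-19 (-2.99 ± 0.47), bli-1 (-2.89 ± 0.44), col-49 (-2.43 ± 0.56) and col-63 (-2.30 ± 0.48). The set test gave adjusted p = 6.06e-06, and adjusted p = 0.0749 with an estimated correlation. Of the collagen family 20 of 115 fell (35 adjusted over the list alone), among them col-181 (-5.30 ± 0.65), col-120 (-5.23 ± 0.87), col-106 (-3.89 ± 0.73) and col-184 (-3.55 ± 0.65), with adjusted p = 9.24e-07 and adjusted p = 0.197 with an estimated correlation. rol-1 (-2.71 ± 0.49), col-124 (-2.82 ± 0.66) and col-140 (-2.68 ± 0.48) fell too. All 3 tested vitellogenins fell, vit-6 (-3.72 ± 0.55), vit-2 (-2.64 ± 0.38) and vit-1 (-1.07 ± 0.24; camera, adjusted p = 4.24e-06, and adjusted p = 0.0215 with an estimated correlation). In the ribosomal protein list 1 of 74 rose (20 adjusted over the list alone), rps-7 (0.22 ± 0.06), with the set shifted up (3.53e-17, but adjusted p = 0.166 with an estimated correlation). No oocyte, germline, sperm, muscle, neuronal or intestinal gene was called by edgeR. DESeq2 did not call col-19 (-2.74, adjusted p = 0.216), col-63 (-1.80), rol-1 (-2.61) or vit-6 (-3.26, adjusted p = 0.0618). limma on rescaled values did not call col-19 (-1.38), col-49 (-2.06), col-63 (-1.40), col-181 (-2.56), col-120 (-2.61), col-106 (-2.44), col-184 (-2.29), rol-1 (-2.01), col-124 (-1.81), col-140 (-1.61), vit-6 (-2.16) or vit-2 (-2.05). With 34 h left out, col-19 (-2.29), col-49 (-2.05), col-63 (-2.01), col-120 (-4.29), col-106 (-3.08), col-184 (-2.92), rol-1 (-2.39), col-124 (-1.97), col-140 (-1.88), vit-1 (-1.07) and rps-7 (0.22) were not called. With 36 h left out, col-49 (-2.46), col-63 (-2.34), col-120 (-4.64), col-106 (-3.30) and col-124 (-2.87) were not. With 32 h left out, col-49 (-2.22), col-63 (-2.32), vit-1 (-1.11) and rps-7 (0.19) were not. col-49, col-63 and col-124 were not called without 20 h either (-2.43, -2.30, -2.82), col-49 and col-124 not without 26 h (-2.43, -2.82), and rps-7 not without any hour from 18 to 30 h (0.22 to 0.23).

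In all, 118 genes were called in the double mutant in the late window, 41 higher and 77 lower, of which 6 and 37 changed at least 2-fold. The count was 1 with no replicate block, 64 without the libraries of 32 h and 24 without those of 34 h. The lin-41 call was lost without pairing by hour (1.09) and with the age from oscillating genes (0.61).

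Comparing the 2 single mutants with the double mutant showed which changes differ between them. lin-41 RNA was higher in let-7(n2853) than in the double mutant by 0.73 ± 0.12 in the late window (adjusted p = 9.06e-05, 5 of 5 hours), while daf-12 differed by -0.02 ± 0.09 (0.905). Both strains had n = 5 libraries in the window. mab-3 was lower in let-7(n2853) by -1.50 ± 0.31 (adjusted p = 9.65e-04), vit-2 by -3.88 ± 0.53, vit-6 by -5.33 ± 0.87, col-175 by -3.99 ± 0.56, col-63 by -2.37 ± 0.52 and the insulin gene daf-28 by -1.83 ± 0.32. The heterochronic gene lin-46 was higher by 1.03 ± 0.19 and gpdh-1 by 1.51 ± 0.30. The largest differences upward were grl-25 (2.73 ± 0.77), col-40 (2.68 ± 0.76), F11D11.3 (2.40 ± 0.33), col-2 (2.38 ± 0.62) and the glucuronosyltransferase gene ugt-66 (2.27 ± 0.37). The vitellogenin list was lower in 3 of 3 and the oocyte list in 10 of 15 genes. The germline list was lower in 10 of 20, the intestinal list in 7 of 15 and the ribosomal protein list in 50 of 74 genes. Of all tested genes 23.02% were called in this contrast, in either direction. Falls of intestinal and ribosomal protein genes were called early too in let-7(n2853) against N2. A change between windows was called for 0 genes between let-7(n2853) and the double mutant. A difference of the let-7(n2853) libraries present in both windows is therefore not excluded for these lists. Set tests gave adjusted p = 0.0403 for vitellogenins (adjusted p = 0.406 with an estimated correlation), 5.74e-05 for oocyte genes (adjusted p = 0.406 with an estimated correlation) and 1.49e-04 for germline genes (adjusted p = 0.387 with an estimated correlation). They gave 8.45e-07 for intestinal genes (adjusted p = 0.0315 with an estimated correlation) and 6.13e-32 for ribosomal proteins (adjusted p = 0.112 with an estimated correlation). In all, 3060 genes were called, 1521 higher and 1539 lower in let-7(n2853) (49.7% higher, 76.2% with limma on rescaled values), and 695 with no replicate block. col-19 was lower by -3.54 ± 0.62, but stood at 0.21 by DESeq2 and was not called without the libraries of 36 h (-1.75), nor were col-40 (2.46) and vit-6 (-2.48). Without those of 32 h, col-40 (2.34) and grl-25 (2.15) were not called. DESeq2 did not call vit-6 (-1.02, adjusted p = 0.531) or col-63 (-2.41, adjusted p = 0.0982), and limma on rescaled values did not call col-19 (-1.10), vit-6 (-1.64) or col-63 (-1.70). Without pairing by hour lin-41 (0.69), mab-3 (-1.53), vit-2 (-4.60), vit-6 (-5.54), col-175 (-3.99), col-63 (-2.15), col-19 (-3.95), lin-46 (0.83), gpdh-1 (1.47), grl-25 (2.32), col-40 (2.47) and col-2 (1.98) were not called, and of the genes named here daf-28, F11D11.3 and ugt-66 were.

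lin-41(xe11) and the double mutant differed late in 12 genes, 7 higher and 5 lower in lin-41(xe11) (557 genes below the threshold before adjustment; other tools were not run on this pair). daf-12 was lower in lin-41(xe11) by -1.30 ± 0.09 (adjusted p = 3.55e-10), the flavin monooxygenase gene fmo-4 by -1.15 ± 0.22 and gst-14 by -1.30 ± 0.26. vit-2 was higher by 1.89 ± 0.38 (0.0439), vit-1 by 1.30 ± 0.24 (0.0137), the scramblase gene scrm-4 by 1.04 ± 0.07 and bath-13 by 1.54 ± 0.17. scrm-4 and bath-13 were as far apart before 28 h: scrm-4 was lower than N2 in the double mutant by -1.01 early and -0.90 late, and bath-13 higher than N2 in lin-41(xe11) by 1.49 early and 1.25 late. lin-41 itself was not called between these strains, whose late means were 75.8 and 76.3 CPM.

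Early effects asked whether the strains differed before 28 h. lin-41 was not called: its early log2 fold changes were 0.09, 0.03 and 0.13 in let-7(n2853), lin-41(xe11) and the double mutant, with adjusted p of 0.651, 1.00 and 0.927. At 26 h, within this window, it already stood at 96.8 CPM in N2 against 148, 124 and 159 in these strains. In this window 2462 genes were called early in let-7(n2853), 1168 higher and 1294 lower (47.4% higher, 70.3% with limma on rescaled values). Among them mab-3 (-1.22), mab-10 (-0.84) and lin-29 (-0.73) were lower, 3 of 3 LIN-41 targets (camera, adjusted p = 0.0143, but adjusted p = 0.351 with an estimated correlation). Of the early calls 1521 were also called late with the same sign and 0 with the opposite sign, and the correlation across all tested genes, which are not independent replicates, was 0.39. The count was 505 with no replicate block and 1503 without the libraries of 26 h. In lin-41(xe11) 9 genes were called early, 6 higher and 3 lower, such as bath-13 (1.49) and K09C6.9 (1.06), and in the double mutant 19, 11 higher and 8 lower, such as K09C6.9 (0.75) and scrm-4 (-1.01). In lin-41(xe11) the early count was 1 with no replicate block and 4 without the libraries of 22 or 24 h. In the double mutant it was 3 with no replicate block, 461 with the age from oscillating genes, which puts its library of 22 h at 29.1 h, 15 with the age from all genes, 5, 6, 5, 4 and 6 without those of 18, 20, 22, 24 and 26 h, and 10 without those of 30, 32 or 36 h. K09C6.9 was singled out after its values were seen.

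The change of an effect from the early to the late window was tested directly. In let-7(n2853) it was called for 11 genes, 6 upward and 5 downward. lin-41 (1.69 ± 0.17, adjusted p = 1.26e-06) and daf-12 (1.27 ± 0.13, 1.26e-06) stood first, with H04M03.3 (2.77 ± 0.42), C11H1.9, C05C8.7 and citk-1 also upward, and col-181 (-8.05 ± 1.42), dao-4 (-4.72 ± 0.95), vrp-1 (-2.14 ± 0.31), ugt-47 and nrf-6 downward. The let-7 target set moved upward (camera, adjusted p = 8.65e-17, and adjusted p = 4.34e-05 with an estimated correlation) and the vitellogenin set downward (3.84e-08, and adjusted p = 0.00258 with an estimated correlation). Seam cell genes moved upward as a set (0.00566, and adjusted p = 0.0351 with an estimated correlation), with none of 13 called singly. Of 22 lists, camera called 4 under both correlations for this change in let-7(n2853), and 2 each in lin-41(xe11) and the double mutant. In the double mutant 1 gene was called, daf-12 (1.21 ± 0.13, adjusted p = 4.81e-06). With the age from oscillating genes 227 genes were called there, but daf-12 was not (0.40, adjusted p = 0.516); with the age from all genes 1 was called, daf-12 (1.17). In lin-41(xe11) 3 were called: lin-41 (1.01 ± 0.17, 0.0148), col-175 (-6.34 ± 1.09) and WBGene00000686 (-5.81 ± 0.74). Leaving out any hour but 26, 34 or 36 h took away the call of lin-41 there (0.91 to 1.01), and leaving out 18 h also that of col-175 (-5.23) and WBGene00000686 (-4.71). col-175 depended on 20, 22 and 34 h too (-6.50, -6.38, -6.11). In let-7(n2853) 0 genes were called by edgeR with the age from oscillating genes (lin-41 0.96, adjusted p = 0.413; daf-12 0.52, adjusted p = 0.547; vrp-1 -1.21), 5 with the age from all genes, and 1 with no replicate block, lin-41 (1.72, adjusted p = 0.0433). There the calls of lin-41, daf-12 and vrp-1 held when any 1 hour was left out, while those of H04M03.3 (2.57), col-181 (-6.02), dao-4 (-4.09), C05C8.7 (0.57), C11H1.9 (0.69), citk-1 (0.54), nrf-6 (-0.53) and ugt-47 (-0.64) were lost without 36 h. dao-4, citk-1 and C11H1.9 were also lost without 18, 22, 24, 26 or 34 h. So were dao-4 and C11H1.9 without 20 h, and dao-4 and citk-1 without 32 h. ugt-47 was lost without 18, 22, 26, 32 or 34 h too, C05C8.7 without 22, 24 or 34 h, col-181 without 18 or 26 h and nrf-6 without 26 h. DESeq2 did not call H04M03.3 (2.69) and dao-4 (-3.51) in let-7(n2853), nor col-175 (-5.63) and WBGene00000686 (-5.17) in lin-41(xe11), and limma on rescaled values did not call col-181 (-3.43), dao-4 (-3.08), col-175 (-2.94) and WBGene00000686 (-2.90). Without the lin-41(xe11) libraries of 18 and 20 h, a choice made after seeing the data, 0 were called there and col-175 turned to 1.77. With all libraries 653 genes lay below the threshold there before adjustment, and DESeq2 called 1. Between let-7(n2853) and the double mutant this change was called for 0 genes by edgeR (766 below the threshold before adjustment; no other tool was run).

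Developmental age was estimated for each mutant library from 20 to 36 h by matching 416 oscillating genes to the N2 time course. let-7(n2853) lay behind N2 by -0.63 ± 0.36 h (SD, n = 9 hours), behind at 8 of 9 hours (exact two-sided sign-flip test, p = 0.00781, adjusted p = 0.0234, smallest possible p = 0.00391). lin-41(xe11) lay at 0.26 ± 0.42 h (exact p = 0.129, adjusted 0.193) and the double mutant at 0.88 ± 2.41 h (exact p = 0.352, adjusted 0.352). The double mutant's mean rests on its 22 h library (7.1 h), without which it was 0.10 h. The let-7(n2853) library of 18 h, outside the hours tested, was put 6.8 h ahead, enough to turn the mean of that strain above 0 if it were included. With all 13295 genes in place of the oscillating ones, let-7(n2853) lay at -0.77 ± 0.46 h and the double mutant at -0.04 ± 0.69 h. N2 libraries left out in turn and placed the same way were off by -0.78 ± 4.39 h (SD, n = 9) by oscillating genes, as far as let-7(n2853), and by 0.03 ± 0.54 h by all genes. The lower age of let-7(n2853) thus rests on the ages from all genes (sign-flip test, adjusted p = 0.0234). That test takes the hours as independent, which the labels do not settle. These ages also include the many genes that differ between this strain and N2. Late-rising genes that are low in let-7(n2853) could themselves lower its age. A delay, such genes and a batch of this strain cannot be told apart here.

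**Figure D2:**
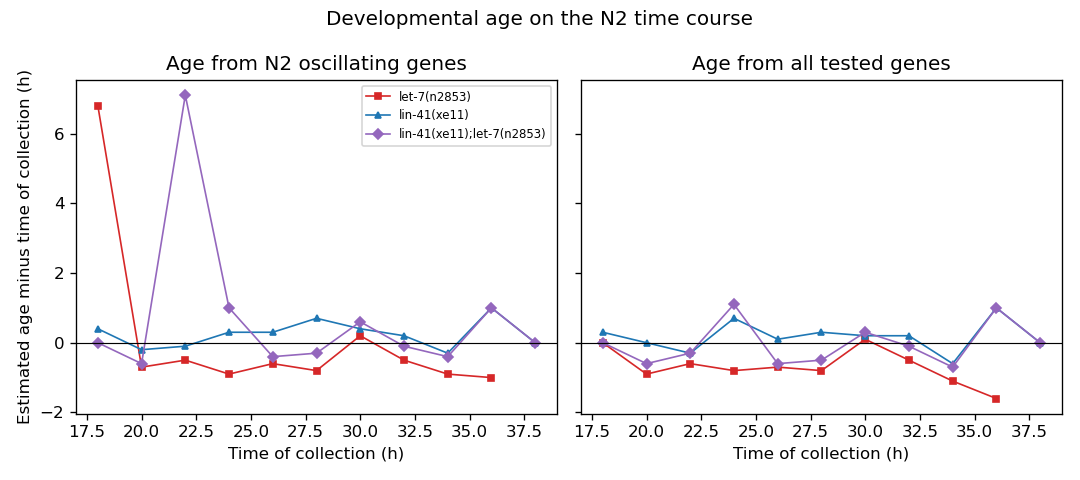
Estimated age minus time of collection in hours (y axis) against the time of collection in hours (x axis); each point is 1 library, each colour 1 mutant strain, with ages from the 416 N2 oscillating genes (left) or all 13295 tested genes (right). let-7(n2853) lay below 0 at 8 of 9 hours from 20 to 36 h by both gene sets.

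The last question was whether a pair of contrasts in disjoint libraries, each with more lin-41 RNA in the strain named first, agree: let-7(n2853) minus the double mutant, and lin-41(xe11) minus N2. The former is the reverse of the effect of xe11 in the let-7(n2853) background, which is the double mutant minus let-7(n2853). Late lin-41 RNA was higher by 0.73 in the former contrast and by 1.03 in the latter. So xe11 went with less lin-41 RNA in let-7(n2853) and with more in N2. Agreement here thus means like changes with more lin-41 RNA, which are opposite effects of xe11 in these backgrounds. Over 13295 genes, the late change between let-7(n2853) and the double mutant had Pearson's r of 0.11 and Spearman's rho of -0.14 with that between lin-41(xe11) and N2, so the measures differ in sign; genes are not independent replicates. Among the called genes, 14 were lower in both against 3.94 expected (Fisher's exact test, adjusted p = 1.23e-05), 3 were higher in both against 1.60 expected (adjusted p = 0.210), and 2 and 3 were called in opposite directions; only these last went the same way as effects of xe11. Where both contrasts share the N2 libraries, overlaps were larger. lin-41(xe11) and the double mutant shared 24 falls (0.197 expected) and 4 rises (0.0432 expected), and let-7(n2853) and the double mutant 65 falls (9.70 expected) and 27 rises (4.28 expected). let-7(n2853) and lin-41(xe11) shared 31 falls (4.28 expected) and 9 rises (1.46 expected). Shared controls raise such overlaps. For lin-41(xe11) and the double mutant r was 0.79. In 20 simulations of noise with shared controls its mean was 0.49 and its highest value 0.53. With the hours split between the contrasts r was 0.31. For let-7(n2853) it was 0.57 with lin-41(xe11) and 0.66 with the double mutant, against simulated means of 0.52 for both and highest simulated values of 0.57 and 0.55, so the r with lin-41(xe11) was equal to the highest of noise to 2 decimals. The covariances, 0.0577 and 0.0777, were larger than the simulated means of 0.0165 and 0.0162. With the N2 libraries split r was 0.29 and 0.27.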

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

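The tests of a separate batch or background, of fewer adult animals or tissues, and of carry-over, with the expected values beside the last pair, and the swaps of strains within hours were chosen only after the results were seen. Each outlier below is a value far from the others of its group of 5; 77 groups were looked at, and chance alone gives about 1 in 20.

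At 36 h lin-41 was 1.46 log2 units above N2 in let-7(n2853), the smallest of 5 late differences, with the nearest other at 1.83. At 30 h col-63 was 3.96 above N2 in lin-41(xe11), while the nearest other late difference was -1.10, so this collagen gene was higher than in N2 in that library and lower in the others. These were the only 2 outliers.

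Samples of 38 h lie outside the comparisons, with 1 library per strain and counting intervals only. There lin-41 was 0.33 log2 units above N2 in lin-41(xe11) (95% interval 0.22 to 0.45, without scaling for composition), and 0.10 (-0.015 to 0.22) in the double mutant. daf-12 was 1.53 above N2 in the double mutant (1.31 to 1.75) and 0.37 in lin-41(xe11) (0.12 to 0.62). With TMM scaling, lin-41 stood at 93.9 CPM in lin-41(xe11), 80.9 in the double mutant and 81.7 in N2, so its difference is small and moves with the scaling.

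The effect of let-7(n2853) differed between the windows, by a test of that difference, for 11 genes. It moved upward for H04M03.3 (2.77, from -1.96 early to 0.81 late), lin-41 (1.69), daf-12 (1.27), C11H1.9 (0.84), C05C8.7 (0.68) and the citron kinase homologue citk-1 (0.56). It moved downward for col-181 (-8.05), dao-4 (-4.72), vrp-1 (-2.14), ugt-47 (-0.69) and nrf-6 (-0.64). H04M03.3 moved alike in lin-41(xe11) (-1.30 early, 0.92 late) and in the double mutant (-1.38 and 0.83), where its change was not called. These comparisons share the N2 libraries, so the change of H04M03.3 is not particular to let-7(n2853). In lin-41(xe11) the effect differed for lin-41 (1.01), col-175 (-6.34, from 3.50 early to -2.84 late) and WBGene00000686 (-5.81, from 3.26 to -2.56), and in the double mutant for daf-12 (1.21). Among 24 regroupings of the libraries, the real one included, 3, 2 and 2 called as many genes as these 11, 3 and 1, with 12, 3 and 1 as the highest others, so chance is not excluded for these counts.

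lin-41(xe11) and the double mutant differ by the let-7 allele, and 12 genes differed between them late. Higher in lin-41(xe11) were vit-2 (1.89), bath-13 (1.54), vit-1 (1.30), scrm-4 (1.04), dhs-7 (0.83), WBGene00020164 (0.81) and the cyclophilin gene cyn-8 (0.41). Lower were daf-12 (-1.30), gst-14 (-1.30), Y39G8B.7 (-1.28), fmo-4 (-1.15) and C48B4.8 (-0.70).

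The first pattern weighed is the 2462 genes called early in let-7(n2853), in a window over which lin-41 was not called though N2 was already lower at 26 h. Depth does not explain them, since 87.8% were also called after thinning the libraries to the others' depth. A delay shared by the whole animal does not account for most of them either, as far as the ages from all genes measure it. With such an age in place of the hour 92.0% were also called. A single age per library, taken from the genes tested, cannot cover a delay that differs between tissues, so timing is not excluded. An effect of the let-7 allele that is alike with and without xe11 should also part the double mutant from lin-41(xe11). Over these genes that correlation was -0.10 in disjoint libraries, which goes against such an effect. An allele effect that depends on lin-41 need not carry over to that pair, so the allele is not excluded. A separate batch or a background difference of the let-7(n2853) libraries is a candidate explanation too, though the batch is not known and coincides with the strain.

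The second pattern is the low cuticle and vitellogenin RNA of let-7(n2853) in the late window, a median of -3.92 over 9 genes. A delay may add to it. By ages from all genes, let-7(n2853) lay at -0.77 h from N2 on average, but at -1.1 h at 34 h and -1.6 h at 36 h. The median was still -3.54 with age in place of the hour, and 9 of 9 genes were called in both fits. A batch that shifts a gene alike at every hour is not the whole cause, since the difference from N2 grew from early to late by a median of -2.60 (fry, p = 0.00268), and of -2.54 over the 4 genes with a CPM of at least 1 early in N2 (p = 0.0385). Fewer animals or tissues of adult stage should lower germline and oocyte RNA too, whose median was -0.30 over 35 genes. The bound set for this test was out of reach. The loss that the cuticle and vitellogenin median implies would lower them by only 1.71, from N2 values taken as a model. They fell by less than that, but the model takes the lost RNA back to the early N2 mean. Animals held between that stage and adulthood could keep more of it, so the test cannot decide. Fewer animals or tissues of adult stage and a block of the adult programme in epidermis and intestine both stay open. A batch that acts on some hours more than others was not tested.

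The last pattern is adult RNA in the lin-41(xe11) library of 18 h, where cuticle genes lay 3.12 and vitellogenins 2.90 log2 units above the other strains. Carry-over from adults should raise oocyte and sperm RNA too, whose medians were 0.19 and 0.86. The smaller one, 0.19, lies under the bound set for this test, but the bound was too strict, since 0.263% of the N2 RNA of 38 h, the share that gives the summed CPM excess of both lists, would raise oocyte genes by only 0.15, sperm genes by 0.71 and cuticle genes by 2.55. It would raise vitellogenins by 5.43, far above the 2.90 seen, so this share does not match all lists. Carry-over remains a candidate explanation, neither shown nor excluded, and col-175, whose change between windows turned to 1.77 without the libraries of 18 and 20 h, may reflect it.

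For the late effects, 1 of 24 regroupings, the real one, called as many genes in each contrast, with 1118 in let-7(n2853), 35 in lin-41(xe11), 23 in the double mutant and 340 between let-7(n2853) and the double mutant as the highest others. The same held for the early effects, with 601, 0 and 0 as the highest others in let-7(n2853), lin-41(xe11) and the double mutant. These regroupings ignore the hour that pairs the libraries. Swaps of the strains within hours give only 16 splits, too few for a share under 0.05. The real counts were 3064, 48, 118 and 3060 late, against 1118, 17, 26 and 118 as the highest others, and 2462, 9 and 19 early, against 414, 0 and 0.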

How the results depend on the processing

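The alternatives that used ages from all tested genes, left out doubtful libraries or let-7(n2853), thinned its counts, rescaled the log2 values or refitted the early effects were chosen after seeing the data. Of the values for named genes under all alternatives, 10191 kept their call and direction or were called in neither fit. A further 654 lost their call, 103 became calls, and the rest changed sign, all but 3 of them with limma on the deposited values. Here and below, sign changes are counted only for values called in at least 1 of the fits compared. The number of trend genes in N2 stayed within 1.5 times its value under the alternatives tried, and the age offset of let-7(n2853) stayed below 0 (-0.77 and -0.69 h). Size factors of DESeq2, the other filters and leaving out histone genes changed no count of calls by more than 1.5 times.

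With no replicate block, calls were 566, 1 and 1 for late effects in let-7(n2853), lin-41(xe11) and the double mutant, 695 between let-7(n2853) and the double, 505, 1 and 3 for early effects, and 1, 0 and 0 for late minus early. By its construction, change between hours then counts as spread. With only the strains compared, which leaves fewer libraries to estimate the spread, calls were 2026, 24 and 56 late, 1556, 4 and 4 early, and 2 and 1 for late minus early in let-7(n2853) and lin-41(xe11).

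limma on the deposited log2 values called 12918 genes late in let-7(n2853), 13038 against the double and 11956 early, with 99.5% of late calls upward and a median shift of 1.11. By construction this is the larger total of the let-7(n2853) values. It also called 20 late in lin-41(xe11), 7 early in the double, and 415, 1 and 2 for late minus early. There the sign changed for 50 values of named genes between let-7(n2853) and N2: act-4 0.65, act-5 0.62, ajm-1 0.89, apl-1 0.96, apx-1 0.0041, asp-1 0.90, car-1 0.89, cbd-1 0.62, cgh-1 0.77, chs-1 0.48, cog-1 0.64, cpr-1 0.47, cyb-1 0.82, cyb-3 0.77, die-1 1.16, dlg-1 0.96, egl-18 0.94, egl-3 0.75, flp-1 0.92, gld-1 0.75, glh-1 0.97, gsp-3 0.79, gsp-4 0.72, his-59 0.79, his-74 0.84, ifb-1 0.98, let-60 1.06, lin-14 1.12, lin-26 0.96, lin-29 0.92, lin-42 0.74, mlc-3 0.73, msp-142 0.59, msp-49 0.15, msp-64 0.014, mtl-2 0.48, myo-1 0.96, myo-2 0.86, nlp-31 0.61, nspd-2 0.31, oma-2 0.24, phat-4 0.69, plk-1 0.99, rpl-31 0.61, rps-20 0.74, rps-21 0.16, rps-29 0.38, ssp-10 0.51, tnt-2 0.94, unc-17 0.79. Between let-7(n2853) and the double it changed for 51: act-4 0.69, act-5 0.48, apx-1 0.023, asp-1 0.73, car-1 0.86, cbd-1 0.73, cgh-1 0.75, cog-1 0.43, cpr-1 0.31, cyb-1 0.88, cyb-3 0.87, daf-12 1.18, die-1 1.07, dlg-1 1.03, egl-3 0.82, elt-1 1.04, glh-1 0.93, gsp-3 0.87, hbl-1 1.03, his-59 0.72, his-71 0.94, ifb-1 1.05, let-60 0.92, lin-14 0.90, lin-29 0.98, lin-42 0.69, lin-66 0.68, mab-10 0.42, mlc-3 0.75, msp-142 0.89, msp-50 0.57, msp-64 0.10, mtl-2 0.28, myo-1 1.03, myo-2 0.93, nlp-31 0.56, nspd-2 0.38, oma-2 0.53, pgl-1 0.94, phat-3 0.64, phat-4 0.69, plk-1 0.95, rpl-31 0.59, rps-20 0.64, rps-29 0.31, rps-7 0.64, sea-2 0.54, spn-4 0.83, tnt-2 0.93, unc-15 0.97, vit-1 0.18. With the values rescaled to 1 total, no named gene called in either fit changed sign. Calls were then 29 late in lin-41(xe11), 7 early in the double, and 1 and 2 for late minus early in lin-41(xe11) and the double.

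The causes of the following changes were not tested. DESeq2's Wald test called 75 late and 25 early in lin-41(xe11), 49 early in the double, and 37, 1 and 3 for late minus early. It changed the sign of col-19 (0.21) and col-119 (0.096) between let-7(n2853) and the double. With 38 h libraries added, calls were 97 late in lin-41(xe11), 229 late and 12 early in the double, and 17 and 2 for late minus early in let-7(n2853) and the double. With the age from oscillating genes, which puts 2 libraries close to a whole rhythm away, they were 60 late and 461 early in the double, and 0, 1 and 227 for late minus early. With the age from all genes, late minus early had 5 in let-7(n2853) and 1 in lin-41(xe11). With the late window from 30 h, late minus early had 61, 9 and 8. Without the lin-41(xe11) libraries of 18 and 20 h, calls were 7 early in the double and 7 and 0 for late minus early in let-7(n2853) and lin-41(xe11), where col-175 turned to 1.77. Without the let-7(n2853) library of 18 h and the double library of 22 h they were 6 early in the double and 6 for late minus early in let-7(n2853). With let-7(n2853) left out they were 12 early in the double and 1 for late minus early in lin-41(xe11), and with its counts thinned 3 for late minus early in the double. Rhythms in N2 were called for 0 genes with a period of 7 h and 23 with 9 h. The correlation of the disjoint contrasts turned to -0.13 in the more highly expressed genes, -0.036 with ages from oscillating genes and -0.027 with ages from all genes, and was 0.042 for late minus early effects.

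Leaving out 1 hour at a time gave 1967 to 3148 late calls in let-7(n2853) (lowest without 36 h), 7 to 50 in lin-41(xe11) (7 without 34 h, 16 without 36 h), 24 to 133 in the double (24 without 34 h, 64 without 32 h) and 2146 to 3097 between let-7(n2853) and the double. Early calls were 1503 to 2495 (lowest without 26 h), 4 to 10 (4 without 22 or 24 h) and 4 to 23 in the double, where leaving out 18, 20, 22, 24 or 26 h gave 5, 6, 5, 4 and 6, and leaving out 30, 32 or 36 h gave 10 each. For late minus early they were 3 to 43 in let-7(n2853): 7, 6, 5, 43, 25, 6 and 3 without 18, 22, 26, 28, 30, 34 and 36 h. They were 0 to 8 in lin-41(xe11): 0, 1, 1, 5 and 8 without 18, 20, 22, 26 and 28 h. They were 1 to 3 in the double: 3, 3 and 2 without 26, 28 and 34 h. Small counts of calls, in lin-41(xe11), in the double and for late minus early, thus rest on single hours. Depth sets a further limit for genes near a CPM of 1, and at these depths a 1.5-fold change between windows was recovered in at most 46.3% of simulated genes.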

Other observations

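The test of a separate batch or background used here was chosen only after the results were seen. daf-12 followed the let-7 allele alone. Its late mean was 32.6 ± 10.8 CPM (SD, n = 5) in N2 and 30.2 ± 6.20 in lin-41(xe11), against 73.5 ± 17.2 in let-7(n2853) and 75.0 ± 20.4 in the double mutant. lin-41 was above N2 with either allele, but lower with both than with let-7(n2853) alone. Its late means were 124 in let-7(n2853), 75.8 in lin-41(xe11) and 76.3 in the double mutant. lin-46, a heterochronic gene, was higher late in let-7(n2853) than in N2 by 0.95 (adjusted p = 7.51e-04). bli-1 had late means of 900 CPM in N2, 56.6 in let-7(n2853), 153 in lin-41(xe11) and 98.9 in the double mutant. vit-2 had 138 ± 238, 0.979 ± 1.00, 118 ± 242 and 24.0 ± 45.4 (SD) in the same order, rising steeply within the window.

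The late difference between let-7(n2853) and the double mutant was set beside the direction of development in N2, whose libraries it does not use. Across 13295 genes, which are not independent replicates, it had Pearson's r of -0.21 and Spearman's rho of -0.20 with the N2 slope per 2 h. Genes that rise in N2 were thus on balance lower in let-7(n2853) than in the double mutant.

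A hypothesis is that lin-41 drives the cuticle change while other let-7 targets drive the fall of vitellogenins. In lin-41(xe11) col-19 and bli-1 fell, though neither was called by limma on rescaled values or without the libraries of 34 or 36 h, nor col-19 by DESeq2. There vit-2 was not called (-0.75), though it was with the age from oscillating genes (-1.32) or from all genes (-1.13). In the double mutant vit-2 fell by 2.64, and its difference from lin-41(xe11) was called (1.89). This may point to a let-7 target other than lin-41 for vitellogenins, but the call in lin-41(xe11) changes with the way time is modelled.

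Another is that the deeper fall of vit-2 in let-7(n2853) than in the double mutant (-3.88) comes from a batch or background of the let-7(n2853) libraries and not from the higher lin-41 RNA there. Over genes called early, the effects of that strain had a correlation of -0.10 with those of the same allele in the xe11 background. Of the 9 cuticle and vitellogenin genes 0 were called early, so this value does not bear on vit-2. The hypothesis was not tested.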
